A study of Drosophila melanogaster with 20 samples.

How the data were processed

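RNA was measured in eye imaginal discs of the third larval instar of Drosophila melanogaster, with 20 Affymetrix oligonucleotide arrays. An imaginal disc is the larval epithelium that forms an adult structure, here the compound eye, and per the labels it was taken at the wandering stage, when larvae leave the food before pupation. Per the labels' protocols, human proinsulin was expressed with the GAL4/UAS system, in which the yeast activator GAL4 switches on a transgene behind UAS sites, and the driver was GMR-GAL4, which is active in the eye disc behind the morphogenetic furrow. Flies carried 1 copy of the transgene and were kept at 25 °C. Total RNA was isolated with the MELT system (Ambion), amplified with the NuGEN Ovation method and labelled with biotin, per the labels' protocols.

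The deposited table holds 1 intensity per probe set and array. The authors' intensity values are linear and all above 0. The submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probes of a probe set, with no version or settings, so the target to which arrays were scaled is unknown. Array means lay between 1194 and 1250 intensity units and array medians between 213 and 286, so the means and not the medians were close, and no further scaling was applied. Signal per probe set depends on probe affinity, so levels were compared between samples and never between genes. The number of arrays limits the precision of each value, and the files used here give no detection call or background level per probe set.

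Of the 18952 probe sets, 183 were array controls and were left out. The platform table pairs 13646 probe sets with exactly 1 gene, 402 with several genes and 4721 with none. Symbols were checked through the Entrez identifiers of a RefSeq gene table (assembly Release 6 plus ISO1 MT). In that check 13543 single-gene probe sets matched, none of their symbols changed, and 103 kept the platform symbol. Chromosomes come from the same gene table. Each of the 11981 genes with a single-gene probe set was represented by the probe set of highest mean over all arrays, and probe sets without a single gene stayed in the tests unnamed. Of 17104 such probe sets the upper 60% by mean value were tested, which gave 10262 probe sets, 8009 of them with a gene name, and a lowest geometric mean of 158 intensity units.

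Samples were grouped by line and sex as the labels give them. There were 5 lines (non-transgenic, WT-6, WT-24, Mut-101, Mut-1), 2 sexes and 2 arrays in each of the 10 groups. The labels call the arrays of a group biological replicates. No array column repeated another, and arrays of a group correlated at 0.978 to 0.993 over the tested probe sets. Comparisons were fitted with limma 3.58.1 in R 4.3.3 on log2 intensity with no pseudocount, using 1 mean per line and sex over all 20 arrays, and eBayes with a trend of variance on mean. The fit had 10 residual degrees of freedom and 3.19 prior degrees of freedom. Lines and sexes were weighted equally in each contrast. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and an adjusted p under 0.05 was called a change. Errors in this fit are the spread between arrays of 1 line and sex, so a p-value does not measure the spread between independent insertion lines. A call was termed line-consistent when all 4 differences between a mutant and a wild-type line had its sign.

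Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The p-values were adjusted over the lists of a comparison. Lists covered ER chaperones and folding enzymes, UPR sensors and the PERK-ATF4 branch, ER-associated degradation, ER translocation and glycosylation, COPI and COPII vesicle transport, apoptosis, JNK targets and regeneration, heat shock proteins (cytosolic, with some mitochondrial members), the proteasome, glutathione and redox enzymes, photoreceptor specification and EGFR signalling, retinal determination and the furrow, cell cycle and DNA replication, insulin and TOR signalling, the ecdysone response, antimicrobial and immune genes, ribosomal proteins, the respiratory chain, and sex-linked and dosage genes. Marker lists of other tissues that a dissection could hold covered fat body, haemocytes, neuroblasts and brain, glia, the antennal disc, salivary gland, muscle, cuticle and peripodial cells, and trachea with ring gland. A list of transgene eye and body colour markers had 0 members tested. The human transgene itself was not analysed here.

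Genes named in the text follow a rule fixed with the design. For C96Y against wild-type proinsulin it takes the 8 largest rises and 8 largest falls among line-consistent calls with a gene name, and for each other comparison the 5 largest rises and 5 largest falls. It adds up to 4 members of each list by smallest p, and Hsc70-3 always. Xbp1, w, roX1 and roX2, also fixed in the rule, had no tested probe set of a single gene and are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

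The groups, the comparisons, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were quantile normalization, centring of each array on its median, no filter or a filter at the upper 40%, a floor at the 20th percentile, every probe set as a separate test, no variance trend, array weights, an additive model of line and sex, only the arrays of the groups compared, replicate numbers as a block, line as a random block, line means, each line left out, and each array left out.

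The scripts were tested on simulated data with the real probe set means and residual spreads, in which 200 probe sets were moved by known amounts. Noise was drawn independently for each probe set and few were moved, so the rates below need not hold for the real arrays. For C96Y against wild-type proinsulin, 60% of probe sets moved by a log2 change of 0.25 were recovered, 86% at 0.5, 96% at 1 and 98% at 2, and 4.49% of the calls were unmoved probe sets. For the interaction of sex and C96Y, recovery at the same sizes was 14%, 52%, 84% and 98%, and for Mut-101 against Mut-1 it was 36%, 82%, 100% and 100%. For wild-type proinsulin against non-transgenic discs it was 52%, 90%, 94% and 98%, with 7.22% unmoved probe sets among the calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.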

Results

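Transcript levels were measured in eye imaginal discs of fly larvae that expressed human proinsulin in the developing eye. Proinsulin is the precursor that pancreatic beta cells fold in the endoplasmic reticulum (ER) before it is cut to insulin, and the C96Y form replaces a cysteine that normally forms a disulphide bond. Discs came from 2 transgenic lines with wild-type proinsulin (WT-6 and WT-24), 2 lines with C96Y proinsulin (Mut-1 and Mut-101) and non-transgenic larvae, for which the labels also list the GMR-GAL4 driver. Each line was sampled in males and females with 2 arrays per sex, so that 8 arrays carried C96Y, 8 carried wild-type proinsulin and 4 carried no transgene. Values are array intensities on a linear scale. Changes are log2 fold changes with standard errors (SE) from limma, with Benjamini-Hochberg adjustment over 10262 probe sets.

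The first principal component, with 19.8% of the variance, placed the 8 C96Y arrays apart from the 12 others. Mut-101 male replicate 2 had the highest median intensity, 286 units, and lay apart from the other arrays on the second component, which held 15.4%. The median within-group residual SD was 0.102 on the log2 scale.

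**Figure D1:**
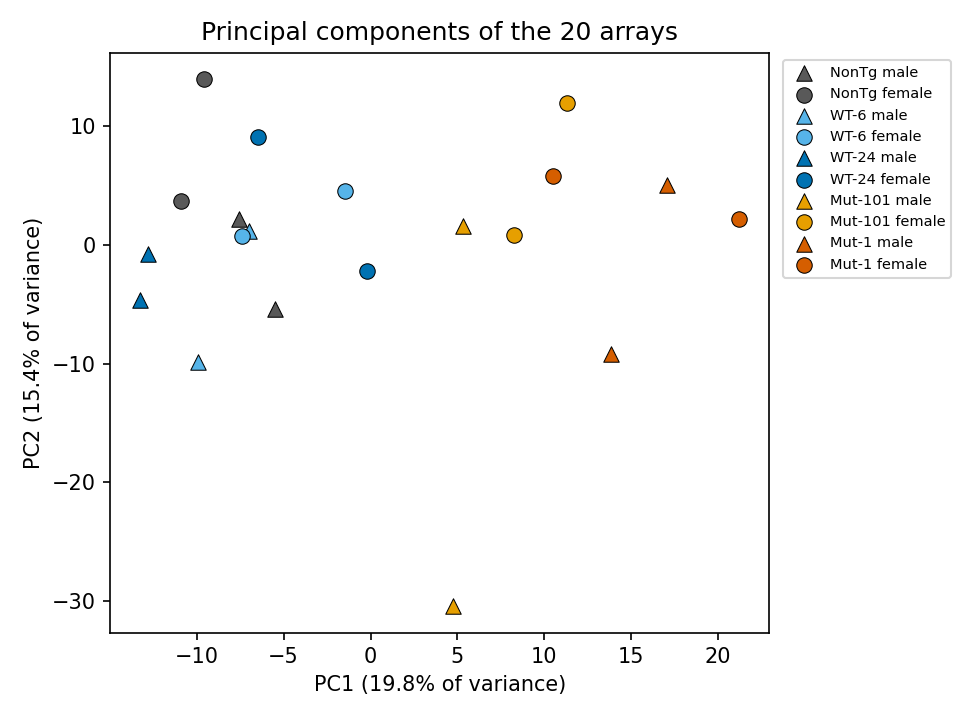
Each point is 1 array, coloured by line, with triangles for males and circles for females, and the axes are the first and second principal components of the tested probe sets (19.8% and 15.4% of the variance). C96Y arrays lie to the right of the 12 other arrays, and Mut-101 male replicate 2 lies at the bottom.

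C96Y was first set against wild-type proinsulin, which asks what the mutant protein changes beyond expression of the normal one. Transgene levels were not analysed, so a difference in dose between the lines cannot be told apart from an effect of the mutation. The largest changes included those of reb and Cda5, which act on chitin, of the growth factor gene daw and of the detoxifying enzyme gene GstE6, beside genes named only by an identifier. The strongest rise was that of CG9313, by a log2 change of 3.81 ± 0.0945 (SE), a 14.1-fold increase (adjusted p = 1.13e-11, limma). Its intensity was 1488 ± 388 in Mut-1 and 433 ± 117 in Mut-101 (SD, n = 4 each), against 55.7 ± 4.44 in the wild-type lines (n = 8) and 53.4 ± 6.42 in non-transgenic discs (n = 4). CG14545 rose 13.4-fold (log2 3.74 ± 0.0864), and since the wild-type levels of both genes were low and no background level was used, these folds are approximate. The gene reb, which acts in chitin deposition, rose 6.62-fold (2.73 ± 0.117). The activin-type ligand gene daw rose by a log2 change of 2.38, from 166 ± 14.7 to 975 ± 532 intensity units (n = 8 each). Cda5, a chitin deacetylase gene, rose 4.04-fold and GstE6, a glutathione S-transferase gene, 3.96-fold. CG13272 (log2 1.87) and CG8620 (1.79) complete the 8 largest rises.

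The largest falls were smaller in size. CG13840 fell by 1.75 ± 0.170 on the log2 scale (adjusted p = 1.43e-05), from 983 ± 104 to 308 ± 112 intensity units (SD, n = 8 each). The cuticle protein genes Cpr97Ea (-1.26) and Cpr12A (-1.07) fell as well. CG6426 (-0.87), acs (-0.81), Vajk1 (-0.81), CG13284 (-0.78) and ana (-0.73), a glial glycoprotein gene, completed the 8 largest falls. The calls of CG6426 and Vajk1 ended when any of 15 and 16 of the arrays, respectively, was left out. Without line Mut-1 the calls of both, of acs and of CG13284 ended, and acs (-0.26), CG13284 (-0.31) and ana (-0.41, still called) had smaller falls. In the fit of all arrays the fall of ana in Mut-101 alone was not called (-0.41, limma adjusted p = 0.155).

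ER folding genes rose as a group in C96Y discs. Of 21 tested ER chaperones and folding enzymes, 13 rose, 1 fell and 7 were not called (14 and 1 adjusted over the list alone). Sil1, a nucleotide exchange factor of the ER chaperone BiP, rose 1.98-fold, from 1628 ± 92.6 to 3289 ± 687 intensity units (SD, n = 8 each; limma adjusted p = 2.11e-08). P58IPK, a BiP cochaperone gene, rose by 0.47 ± 0.0414 (SE), Manf, a secreted ER stress factor gene, by 0.39 ± 0.0336, and the disulphide isomerase gene CaBP1 by 0.30 ± 0.0303. Ero1L, whose product oxidises disulphide isomerases, rose by 0.72 and was picked after its value was seen, as was CG14715, the member that fell (-0.08). Hsc70-3, which encodes BiP, rose 1.09-fold, by 0.13 ± 0.0201 (adjusted p = 0.000856), from an intensity of 14980 to 16347. The list stood above other genes by camera (adjusted p = 1.85e-08) and not with an estimated correlation (adjusted p = 0.272 with an estimated correlation), and fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.000498.

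Genes of vesicle transport between the ER and the Golgi rose in parallel. Of 23 COPI and COPII genes 13 rose, none fell and 10 were not called (16 rose adjusted over the list alone), among them Tango14 (log2 0.39 ± 0.0419), Slh (0.43 ± 0.0495, with its other probe set at 0.16 and an adjusted p of 0.0539), Sec22 (0.39 ± 0.0471) and deltaCOP (0.25 ± 0.0375). For this list the camera adjusted p was 1.42e-07, with an adjusted p = 0.272 with an estimated correlation. In ER-associated degradation, which removes misfolded proteins, 6 of 15 genes rose and none fell (8 rose and 1 fell adjusted over the list alone). Der-1 rose by 0.39 ± 0.0292, Herp by 0.34, Hrd3 by 0.30 and Der-2 by 0.21, with a camera adjusted p of 0.00425 (adjusted p = 0.549 with an estimated correlation). Among 22 genes of ER translocation and glycosylation 8 rose and 1 fell (10 and 2 adjusted over the list alone). The signal peptidase genes Spase25 and Spase12 rose by 0.19 and 0.15, and Sec61beta by 0.20. The camera adjusted p was 0.0110 (adjusted p = 0.629 with an estimated correlation).

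The list of UPR sensors and the PERK-ATF4 branch went both ways, with 4 of 15 members up and 2 down (5 and 3 adjusted over the list alone; camera adjusted p = 0.263, fry adjusted p = 0.000731). AsnS, the asparagine synthetase gene, rose 2.17-fold, from 391 ± 50.4 to 846 ± 97.3 intensity units (SD, n = 8 each; limma adjusted p = 1.11e-06). Gadd45 rose by 0.51, trbl by 0.24 and the kinase gene PEK by 0.23. The serine synthesis genes aay and CG11899 fell by 0.51 and 0.15, and both were picked after their values were seen.

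**Figure D2:**
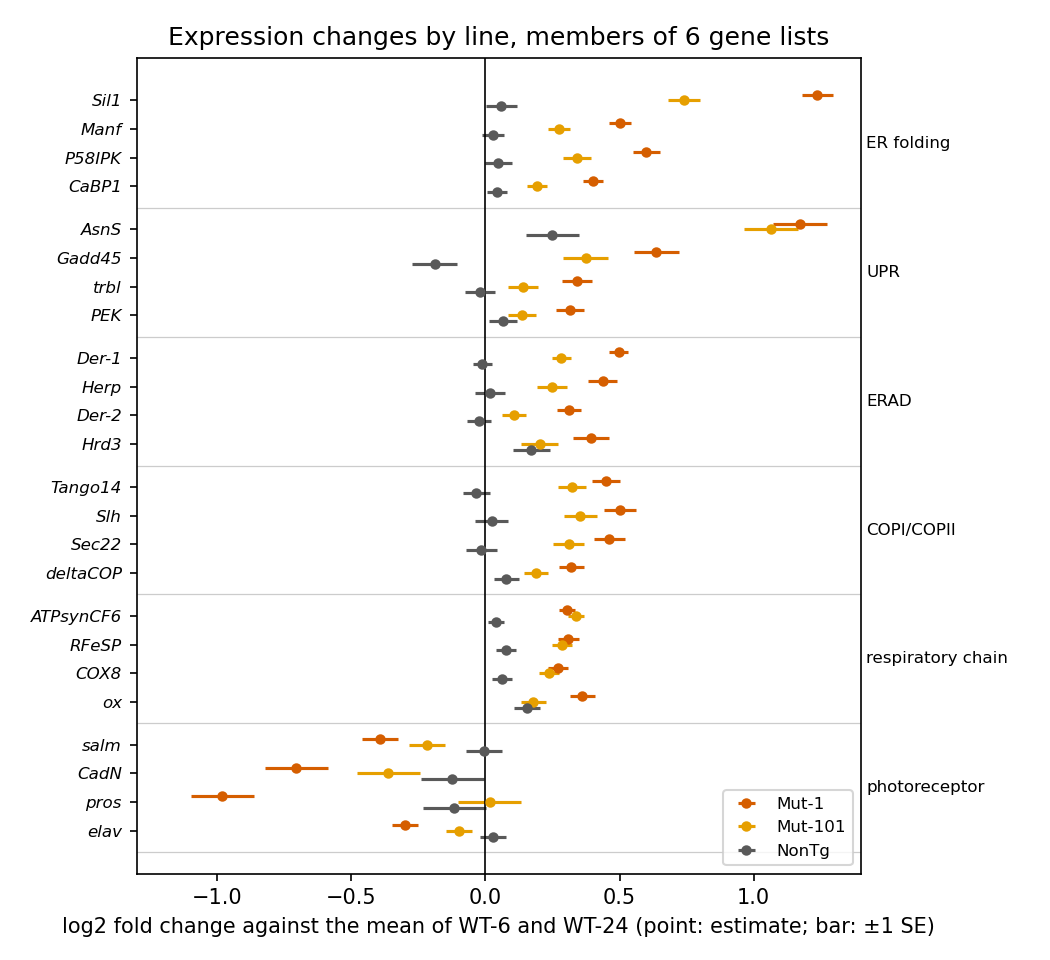
Points give the log2 fold change of each line against the mean of WT-6 and WT-24, with bars of 1 SE, for the 4 members with the smallest p in 6 gene lists. Sil1 stands at 1.24 in Mut-1, 0.74 in Mut-101 and 0.06 in non-transgenic discs, while pros is lower in Mut-1 (-0.98) and stands at 0.02 in Mut-101.

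Photoreceptor genes fell more often than they rose. Of 24 genes of photoreceptor specification and EGFR signalling 11 fell and 3 rose (12 and 4 adjusted over the list alone), with a camera adjusted p of 0.0444 (adjusted p = 0.752 with an estimated correlation; fry adjusted p = 0.163). The transcription factor gene salm fell by 0.31 ± 0.0546, the cadherin gene CadN by 0.53 ± 0.0958 and the neuronal gene elav by 0.20 ± 0.0394. None of these 3 was called in Mut-101 alone (salm -0.22, CadN -0.36, elav -0.10; limma adjusted p = 0.0649, 0.0806 and 0.236), and their calls ended without Mut-1. The call of pros (-0.48) came from Mut-1, where it fell by 0.98, while its log2 change was 0.0165 with Mut-1 left out. The members that rose were ro (0.15), boss (0.23) and sina (0.17), picked after their values were seen. Of 14 genes of retinal determination and the furrow, 5 fell and 1, tsh (picked after its value was seen), rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.136, fry adjusted p = 0.0301). E(spl)mdelta-HLH fell by 0.21, so by 0.14, and toy and hh by 0.10 each, and the call of toy ended without Mut-101 female replicate 2. The direction of toy differed between its probe sets, with another that rose by 0.37 (limma adjusted p = 0.0239) and another that fell by 0.15. Its fall of 0.10 was also no larger than the median change of the 55 tested genes of chromosome 4 (-0.10), to which toy belongs. Without line Mut-1 the calls of E(spl)mdelta-HLH, so, hh and toy ended.

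Members of the respiratory chain, glutathione and cell cycle lists changed as well, though against non-transgenic discs the respiratory chain list was mixed, as given below. Of 58 respiratory chain genes 12 rose and none fell (14 rose adjusted over the list alone), with ATPsynCF6 up by 0.32 ± 0.0247, RFeSP by 0.30, ox by 0.27 and COX8 by 0.25 (camera adjusted p = 0.00232; adjusted p = 0.629 with an estimated correlation). Of 23 glutathione and redox genes 8 rose and 1 fell (10 and 1 adjusted over the list alone), with GstE5 at 0.68, GstE1 at 0.39 and the thioredoxin gene Trx2 at -0.10 (camera adjusted p = 0.00425; adjusted p = 0.272 with an estimated correlation). Of 19 cell cycle and replication genes 6 rose and 1, CycE (-0.23, picked after its value was seen), fell, with the same counts adjusted over the list alone. Orc2 rose by 0.24, Mcm3 by 0.22, Mcm2 by 0.21 and aurB by 0.18 (camera adjusted p = 0.0242; adjusted p = 0.691 with an estimated correlation; fry adjusted p = 0.0612), and these calls of Orc2, Mcm3, Mcm2 and aurB all ended without line WT-24.

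Cell death and stress lists outside the ER were not called by camera, but many of their members could not be tested. Tested were 16 of 23 apoptosis genes, 15 of 22 JNK and regeneration genes and 10 of 25 heat shock genes. The apoptosis genes rpr and hid had no probe set of a single gene, so their response is unknown. In apoptosis 3 of 16 genes rose (morgue 0.15, Dark 0.20, Debcl 0.14; the other probe set of Dark was at -0.05, adjusted p = 0.696) and egr, the fly TNF gene, fell by 0.23 (same counts adjusted over the list alone; camera adjusted p = 0.760). In JNK targets and regeneration Gadd45 and kay (0.16) rose and bsk fell by 0.12 among 15 genes (same counts adjusted over the list alone; camera adjusted p = 0.905), with a median of -0.03 against a mean of 0.02. The heat shock list had 2 of 10 members up, Hsp68 (0.21) and the mitochondrial Hsc70-5 (0.08), in both adjustments, and their mean was -0.00 while the median and the test were positive (camera adjusted p = 0.660). Of 31 proteasome genes 6 rose, among them Rpt4 (0.12), Rpn7 (0.11) and Prosalpha3 (0.11), and none fell, in both adjustments (camera adjusted p = 0.355). Insulin and TOR signalling had ImpL2 (0.25) and Tsc1 (0.16) up and S6k (-0.14) and bmm (-0.48) down among 10 genes (2 up and 3 down adjusted over the list alone; camera adjusted p = 0.386). The ecdysone response had 2 of 21 up, Eip63E (0.35) and Edg78E (0.38), and 2 down, MsrA (-0.31) and usp (-0.12), in both adjustments, and its mean of 0.03 was positive while its median of -0.05 and the test were negative (camera adjusted p = 0.592). The ribosomal list had 6 of 38 members up, by 0.03 to 0.06, and none down (5 up adjusted over the list alone), and its mean was -0.01 while the median and the test were positive (camera adjusted p = 0.660). The calls of Debcl, Hsp68, Hsc70-5, S6k and bmm each ended when 1 of several arrays was left out. In the antimicrobial list 0 of 8 genes and in the sex-linked list 0 of 7 were called by limma in either adjustment (camera adjusted p = 0.748 and 0.760), with 1 and 2 at an unadjusted p under 0.05.

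Markers of other tissues were compared in the same discs. Some lists share members, and lz and pros are also in the photoreceptor list, so in eye discs they need not mark another tissue. Of 9 fat body genes and 9 salivary gland genes 0 were called by limma in either adjustment and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.760 and 0.386), and of 14 muscle genes 0 were called and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.263). Of 16 haemocyte markers, Hml rose by 0.51 and NimC1 and lz fell by 1.14 and 0.12, in both adjustments (camera adjusted p = 0.748). NimC1 was not line-consistent, with 1042 ± 221 intensity units in WT-6 and 223 ± 84.4 in WT-24 (SD, n = 4 each), and the calls of Hml and lz ended without 1 of several arrays. Among 13 neuroblast and brain genes dpn (-0.30), nerfin-1 (-0.38) and pros fell and none rose (5 fell adjusted over the list alone; camera adjusted p = 0.212). Of 10 glial genes moody rose by 0.51, and Nrx-IV (-0.17) and nrv2 (-0.07) fell (2 up and 2 down adjusted over the list alone; camera adjusted p = 0.994), with a mean of 0.02 against a median of -0.02 and a test direction that were negative. The call of nrv2 ended without any of 15 arrays. In the antennal disc list salr (-0.33) and Dll (-0.13) fell among 10 (3 fell adjusted over the list alone; camera adjusted p = 0.0547, fry adjusted p = 0.00121). Among 40 cuticle and peripodial genes 4 rose and 4 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.422), and Cpr51A fell by 0.34. In the list of trachea and ring gland markers 4 of 8 fell in both adjustments, serp (-0.33), Gasp (-0.13), obst-A (-0.26) and verm (-0.21), all genes of chitin assembly or modification, where the call of verm ended without any of 11 arrays (camera adjusted p = 0.0144; adjusted p = 0.549 with an estimated correlation). The calls of Gasp, obst-A and verm ended without line Mut-1 and that of serp without WT-6.

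In total 2058 probe sets differed between C96Y and wild-type discs by limma, 1177 higher and 881 lower, of which 32 and 8 changed more than 2-fold. Of these calls 1923 (1117 higher, 806 lower) had the same sign in all 4 pairs of lines, and of the 95 named calls 82 held with each array left out in turn. Without line Mut-1, 50 of these 95 kept their call and 45 lost it or changed sign, among them, beside those given above, trbl, PEK, Der-2, Hrd3, GstE1, GstE5, GstE6, Dark, Debcl, egr, bsk, Hsp68, Hsc70-5, ImpL2, S6k, bmm, usp, Hml, lz, nerfin-1, Nrx-IV, nrv2, Cpr51A, Orc2 and Mcm2. Without Mut-101, WT-24 or WT-6 84, 66 and 77 were kept, and calls lost included Rpt4, Rpn7 and Prosalpha3 without WT-24, kay, morgue, Trx2 and NimC1 without WT-6, and Dll, MsrA and Tsc1 without Mut-101. The count was 604 with arrays centred on their medians, 724 without line Mut-1, 1049 without line WT-24 and 643 with the description number as a block. Description numbers were shared only in part between the lines, so this block lowers the precision of differences between lines. With 1 mean per line, 2 lines against 2, limma called 0 probe sets, so the calls rest on the spread between arrays of a line and not on that between insertion lines. Without the 2 arrays that held fat body transcripts, an alternative chosen after seeing the data, the count was 1678.

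Wild-type proinsulin was set against non-transgenic discs to ask what expression of the normal protein changes, at a transgene level that was not analysed. Few genes differed, and ER genes were not among them. The homeobox gene vis was higher with wild-type proinsulin by a log2 difference of 1.54 ± 0.129 (SE; limma adjusted p = 0.000193), at 369 ± 40.9 intensity units (SD, n = 8) against 156 ± 112 (n = 4). Its level varied widely between the non-transgenic arrays and, as given below, differed between the mutant lines. A difference between lines therefore cannot be told apart from an effect of the transgene on vis. GstT3 was 0.79 ± 0.0972 higher, and Zip102B and fuss, both on chromosome 4, were 0.46 and 0.45 higher. Arpc1, an actin nucleation gene, was lower (-0.82 ± 0.106), as were pins (-0.34) and ssx (-0.21). Hsc70-3 stood at -0.00 ± 0.0247. The change of pins was 0.00385 with line WT-6 left out. In all 28 lists tested 0 members were called over all genes by limma, against 32 of 519 member tests with an unadjusted p under 0.05. Adjusted over the list alone 1 sex-linked and 1 fat body gene were higher. Camera placed the proteasome (adjusted p = 0.00127) and respiratory chain (0.00198) below other genes and the sex-linked list (0.0138) above them. None of these held (adjusted p = 0.934, 0.934 and 0.411 with an estimated correlation).

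The count of probe sets that differed was 11, 5 higher and 6 lower, with 733 at an unadjusted p under 0.05 where 513 would arise by chance. Only 3 of the 7 named calls held with each array left out. The count was 3 without non-transgenic female replicate 2, which ended the calls of Zip102B, pins and ssx (that of fuss ended without any of 13 arrays), and 27, 23 and 25 without non-transgenic male replicates 1 and 2 and female replicate 1. It was 6 with median centring, 2 with only the arrays compared or with the description number as a block, 4 with line as a random block and 28 without line WT-6.

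C96Y was then set against non-transgenic discs, the comparison in which the transgene is absent altogether. The genes with the largest rises were those above, CG9313 (log2 3.88 ± 0.116), CG14545 (3.68 ± 0.106), reb (2.82), daw (2.17) and Cda5 (2.11). Cpr97Ea fell by 1.59 ± 0.148, CG13840 by 1.48, NimC1 by 1.07, pst by 0.93 and Cpr12A by 0.89. Of 21 ER chaperones and folding enzymes 10 rose and none fell (12 rose adjusted over the list alone), with Sil1 at 0.93 ± 0.0583, P58IPK at 0.42, Manf at 0.36 and Hsc70-3 at 0.12 (camera adjusted p = 8.28e-08; adjusted p = 0.378 with an estimated correlation). Of 23 COPI and COPII genes 6 rose and none fell (7 rose adjusted over the list alone; camera adjusted p = 1.07e-05; adjusted p = 0.378 with an estimated correlation). AsnS rose by 0.87, Gadd45 by 0.70, Der-1 by 0.40 and ATPsynCF6 by 0.28, and elav fell by 0.23, a call that ended without non-transgenic female replicate 2. The calls of NimC1 and Cpr12A ended without non-transgenic male replicate 2 and that of pst without any of 8 arrays. Of 24 photoreceptor genes 4 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.216). Of 58 respiratory chain genes 5 rose and 2 fell, in both adjustments (camera adjusted p = 0.216), whereas against wild-type proinsulin 12 rose and none fell. Of 31 proteasome genes limma called 0 in either adjustment and 5 were lower at an unadjusted p under 0.05, whereas against wild-type proinsulin 6 rose. Non-transgenic male replicate 2 had the highest fat body score of all arrays, 2.44 above the mean of the arrays on the log2 scale.

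By limma 1185 probe sets differed, 698 higher and 487 lower. The count was 581 without non-transgenic male replicate 2, 572 without non-transgenic female replicate 2, 515 without the 2 arrays with fat body transcripts, 734 with line as a random block, 338 without line Mut-1 and 271 with the description number as a block. With arrays centred on their medians it was 330, of which 249 were higher and 81 lower. The 2 comparisons against non-transgenic discs share their controls. Their log2 changes correlated across genes at r = 0.50, against a simulated 0.67 with no effects, and the covariance was 0.0143 against a simulated 0.0102. When the controls were split between the comparisons, r was 0.07 and 0.02. Shared calls were 4 rises and 4 falls, where independent lists would give 0.340 and 0.285, a value that leaves out the shared controls, so the excess does not show a shared effect.

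The effect of C96Y was compared between the sexes. In males 834 probe sets differed between C96Y and wild-type discs (575 higher, 259 lower) and in females 672 (421 higher, 251 lower). CG14545 and CG9313 rose most in both, by 4.29 and 4.08 in males and by 3.20 and 3.55 in females, and reb rose by 2.88 and 2.57. In males daw rose by 2.71 and Cda5 by 2.36, and in females CG32249 rose by 2.29 and GstE6 by 2.08. CG13840 fell by 2.02 in males and 1.49 in females, Cpr97Ea 2.84-fold and 2.02-fold, and vis by 1.02 and 1.19, where vis was low in Mut-1 and not in Mut-101 (70.4 ± 3.70 intensity units in Mut-1, 415 ± 33.1 in Mut-101; SD, n = 4 each). Further falls were those of acs (-1.13) and Jhbp1 (-1.05) in males, and of NimC1 (-1.49) and Cpr12A (-1.26) in females. ER chaperones and folding enzymes rose in both, 12 of 21 in males (14 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.39e-10; adjusted p = 0.314 with an estimated correlation) and 8 of 21 in females (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.12e-06; adjusted p = 0.413 with an estimated correlation). Sil1 rose 2.14-fold in males and 1.84-fold in females, and AsnS 2.35-fold and 2.01-fold. COPI and COPII genes rose in 11 of 23 cases in males and 5 in females (12 and 9 adjusted over the list alone; camera adjusted p = 4.13e-08 and 1.26e-05; adjusted p = 0.314 and 0.413 with an estimated correlation). Photoreceptor genes fell in 3 of 24 cases in males and 4 in females, and none rose (5 fell and 3 rose in males and 9 fell and 1 rose in females adjusted over the list alone). For these genes the camera adjusted p was 0.197 in males and 0.0141 in females (adjusted p = 0.663 with an estimated correlation in females). Muscle markers lay lower in C96Y males than in wild-type males, with a median of -0.59 and 0 of 14 called by limma (camera adjusted p = 0.00976; adjusted p = 0.723 with an estimated correlation).

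The interaction of sex and C96Y, tested by limma, called 0 probe sets, with 341 at an unadjusted p under 0.05 where 513 would arise by chance, so the sexes were not shown to differ at any gene. The count was 1 with a floor on low values and 3 with the description number as a block or without WT-24 male replicate 1. It was 1 without WT-24 male replicate 2, Mut-101 female replicate 1, Mut-1 male replicate 1 or Mut-1 female replicate 2. The calls of acs, Jhbp1 and Cpr12A in males and of CG32249 in females ended when 1 of several arrays was left out, and that of GstE6 in males (1.90) ended without Mut-1 male replicate 2. In males the count was 359 without Mut-1 male replicate 2, 429 without WT-24 male replicate 2, 395 with only the arrays compared, 197 with median centring and 267 with the description number as a block. In females it was 245 without Mut-101 female replicate 2, 314 without Mut-1 female replicate 2, 308 without WT-6 female replicate 1, and 352 and 309 without WT-24 female replicates 1 and 2. It was 373 with only the arrays compared, 53 with the description number as a block and 126 with median centring, of which 101 were higher and 25 lower.

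The 2 lines with C96Y differed from each other, only in part in the size of the response. Of the 358 probe sets that differed, 186 were line-consistent C96Y calls. Among the genes named here tut and GstD3 also differed between the wild-type lines (log2 2.28 and 0.57 in WT-24 relative to WT-6). In Mut-101 relative to Mut-1, CG14545 was lower (log2 -2.45 ± 0.122, SE; limma adjusted p = 2.46e-07), as were reb (-1.92 ± 0.165), GstE6 (-1.80), CG9313 (-1.79) and CG10184 (-1.77). Higher in Mut-101 were vis (2.56 ± 0.149), tut (2.52 ± 0.260), acs (1.11), CG42565 (1.07) and sv (1.07). Of 21 ER chaperones and folding enzymes 4 were lower in Mut-101, Sil1 (-0.50), P58IPK (-0.26), Manf (-0.23) and CaBP1 (-0.21), and none higher (6 lower adjusted over the list alone; camera adjusted p = 0.000571; adjusted p = 0.754 with an estimated correlation). Of 23 glutathione and redox genes 5 were lower and none higher (6 lower adjusted over the list alone), among them GstD3 (-0.63) and GstE5 (-0.75), with a camera adjusted p of 0.000571 (adjusted p = 0.139 with an estimated correlation). Of 24 photoreceptor genes 4 were higher, pros (1.00), sev (0.61), futsch (0.27) and aos (0.20), and none lower, while the other probe sets of futsch stood at -0.01 and 0.04 and were not called (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00121; adjusted p = 0.754 with an estimated correlation). Salivary gland markers lay lower in Mut-101, with a mean of -0.64 and 1 of 9 called, and neuroblast and brain markers higher, with a mean of 0.17 and 1 of 13 called, in both adjustments (camera adjusted p = 0.0263 for each, adjusted p = 0.754 with an estimated correlation). The neuroblast and brain gene called was pros, which is also in the photoreceptor list.

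By limma 358 probe sets differed between the mutant lines, 136 higher and 222 lower in Mut-101. Against the wild-type lines 1839 probe sets were called in Mut-1 and 757 in Mut-101, with 526 called in both with the same sign. Of the 1923 line-consistent C96Y calls 1371 (71.3%) had the larger change in Mut-1, with median sizes of 0.21 and 0.16. Of the 186 line-consistent calls that also differed between the 2 lines 179 were larger in Mut-1. The count of 358 became 198 without Mut-101 male replicate 2, 204 and 212 without Mut-101 female replicates 1 and 2, 167 without Mut-1 male replicate 2 and 218 without Mut-1 female replicate 2. It was 180 with median centring, 225 with only the arrays compared and 5 with the description number as a block, numbers that the 2 lines share only in part. Of the genes above the calls of CaBP1, Manf, P58IPK, GstE5, GstE6, acs, sv, futsch and aos ended without 1 of several arrays.

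**Figure D3:**
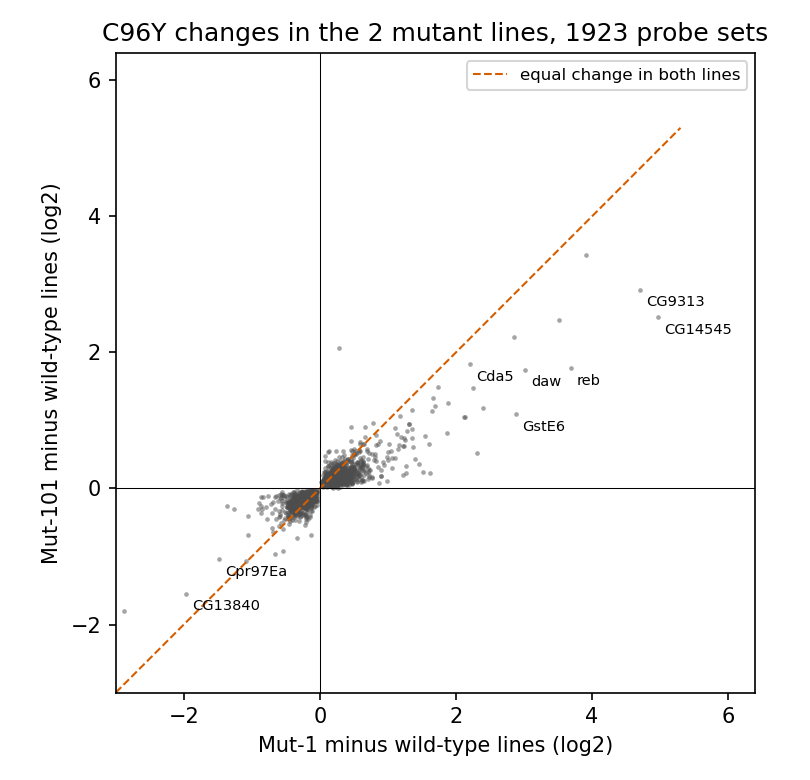
Each point is 1 of the 1923 line-consistent probe sets, with the log2 difference from the wild-type lines in Mut-1 on the x axis and in Mut-101 on the y axis; the dashed line marks equal changes. For 71.3% of the points the change was larger in Mut-1, and CG14545 lies at 4.97 and 2.52.

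The 2 lines with wild-type proinsulin differed at fewer genes. In WT-24 relative to WT-6, CG17109 was higher by 3.22 ± 0.491 (log2; limma adjusted p = 0.00379), tut by 2.28 ± 0.260, CG7607 by 1.06, Mrp4 by 0.99 and CG33307 by 0.95. Lower were NimC1 (-2.28 ± 0.286), a phagocytosis receptor gene of haemocytes, l(2)34Fc (-1.56), Tep3 (-1.26), CG8319 (-0.92) and CG33640 (-0.84). GstD3 was higher by 0.57, sina by 0.41 and Cpr92A by 0.85, and serp was lower (-0.34). Of 21 ER chaperones and folding enzymes 0 were called by limma and 0 had an unadjusted p under 0.05, and Hsc70-3 stood at 0.02. Haemocyte markers as a list lay lower in WT-24 (camera adjusted p = 0.00590), with NimC1 the member called, as did the proteasome (0.00353), the respiratory chain and muscle markers (0.0254 each), and none of these held (adjusted p = 0.949 with an estimated correlation). In all 98 probe sets differed, 61 higher and 37 lower. The count was 61 without WT-6 female replicate 2, 59 without WT-24 female replicate 1, 65 without WT-24 female replicate 2, 43 with median centring and 2 with the description number as a block.

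**Figure D4:**
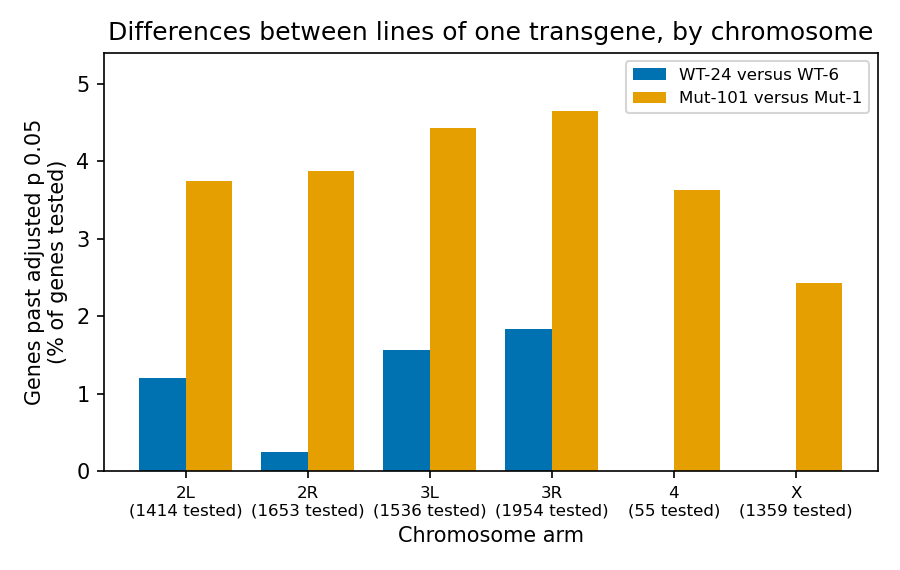
Bars give the percent of tested genes on each chromosome arm that differed between the 2 lines of each transgene. Between WT-24 and WT-6 no gene was called on the X chromosome (0 of 1359) or on chromosome 4 (0 of 55). The other arms ran from 0.24% on 2R to 1.84% on 3R. Between Mut-101 and Mut-1 the X chromosome had 2.43%, against 3.64% to 4.66% on the other arms.

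Males were compared with females over all 5 lines, which also checks the sex labels. The splicing factor target dsx, read by a probe set picked after its values were seen, had 38.3 ± 5.88 intensity units in 10 males and 1808 ± 181 in 10 females, with no overlap. The dosage compensation gene msl-2 was higher in males by 0.71 ± 0.0578 (SE; limma adjusted p = 4.96e-06), at 3171 ± 234 against 1940 ± 219 units (SD, n = 10 each), Sxl was higher by 0.32 and 0.25 at 2 probe sets and lower at another (-1.23, adjusted p = 0.00173), and the splicing regulator gene tra was lower (-0.44). Of 7 sex-linked and dosage genes 3 were higher and 2 lower in males, in both adjustments. FucTC (2.63-fold), corolla (log2 1.12), CG32572 (0.93), olf186-M (0.83) and Act87E (0.82) were the 5 largest rises, and CG1835 (-2.28 ± 0.0911), kek5 (-1.33), Rbm13 (-1.29), Nplp2 (-1.17) and CG32793 (-1.14) the 5 largest falls. The other probe set of kek5 was at -0.17 (adjusted p = 0.387). Muscle markers lay higher in males, with a median of 0.70, 2 of 14 called and 10 adjusted over the list alone (camera adjusted p = 0.0133; adjusted p = 0.866 with an estimated correlation), and bt was higher by 0.67. Proteasome (0.00742) and respiratory chain genes (0.00330) lay lower in males by camera, and neither held (adjusted p = 0.866 with an estimated correlation).

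In total 1264 probe sets differed between the sexes, 796 higher and 468 lower in males, and this split depended on the scaling. Quantile normalization gave 310 higher and 520 lower, and median centring, which moved the median of all probe sets by -0.10, gave 100 higher and 615 lower. Of 1359 X-chromosome genes 291 (21.4%) were lower in males, against 1.45% to 1.94% on the arms of chromosomes 2 and 3, and 153 (11.3%) were higher, against 5.14% to 6.23% on those arms. On chromosome 4, 6 of 55 genes (10.9%) were higher in males and 0 lower, so the share of higher genes was not particular to the X. The count was 710 without WT-6 female replicate 2, 725 without Mut-101 female replicate 2, 841 without Mut-1 male replicate 1, 576 with the upper 40% of probe sets (262 higher, 314 lower) and 366 with the description number as a block, and the calls of Nplp2 and olf186-M ended without 1 of several arrays.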

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

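Tests of the X chromosome count against tissue composition or scaling, and of the lines as the source of high spok levels, were chosen only after the result was seen.

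The differences between the 2 mutant lines, 358 probe sets, were larger than other arrangements of their arrays gave. In a fit of split and sex, 1 of 34 splits of the 8 arrays, the real one, gave as many calls (289, with 0 the highest of the others). This argues against chance among arrays, but 34 splits allow no smaller share. Description numbers of the 2 lines overlapped only in part, and with them as a block few calls remained, as given above. That loss cannot tell a batch from the lower precision of a block only partly shared by the lines. Most C96Y changes were larger in Mut-1. With Mut-101 male replicate 2 left out 66.2% of the line-consistent calls were still larger in Mut-1, which argues against that array as the whole cause. With all arrays kept, 76.0% were larger in Mut-1 in males and 60.8% in females, so the excess was smaller in females. A compressed scale of the Mut-101 arrays would also shrink the sex differences in that line. Of 1005 sex-difference calls outside the C96Y calls only 41.5% were larger in Mut-1. Mut-101 male replicate 2, the array of highest median, was kept in this count. The count was not repeated without that array, so it cannot decide on a compressed scale. A higher level of the transgene in Mut-1, or a difference in genetic background, stays open and was not tested, because the human transgene was not analysed here.

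Several gene lists differed between the mutant lines by camera, each with the adjusted p and the mean log2 difference of Mut-101 from Mut-1. ER chaperones and folding enzymes (0.000571, mean -0.11), glutathione and redox genes (0.000571, -0.29), COPI and COPII genes (0.0224, -0.06), respiratory chain genes (0.0360, -0.02) and salivary gland markers (0.0263, -0.64) were lower in Mut-101. Photoreceptor genes (0.00121, 0.14), neuroblast and brain markers (0.0263, 0.17) and markers of trachea and ring gland (0.0320, 0.24) were higher. The photoreceptor list and the neuroblast and brain list share pros, so they are not separate evidence. With an estimated correlation none passed, at an adjusted p of 0.139 for the glutathione list and 0.754 for the other 7, while fry, which tests a list against no change, gave 0.00326 for the glutathione list and 0.134 to 0.430 for the others. The trachea and ring gland list mixes chitin genes with ring gland genes such as sad. The ring gland gene spok was high in 2 of 4 Mut-101 and 0 of 4 Mut-1 arrays, as given below.

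Between the sexes, 3 lists differed in their response to C96Y by camera. ER chaperones and folding enzymes (adjusted p = 0.000366, mean 0.10) and haemocyte markers (0.00126, mean 0.27) had more positive changes in males, and muscle markers (0.000324, mean -0.72) more negative ones. With an estimated correlation all had an adjusted p of 0.542, and fry gave 0.629.

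Among 50 sets of 4 arrays of 1 line screened for an array far from the others, 4 stood out, where chance would give 2.5, since about 1 set in 20 (5%) is picked by chance. WT-6 male replicate 2 had a mean haemocyte marker score of -0.0257, against 0.22 to 0.23 in the other WT-6 arrays. Non-transgenic female replicate 2 had a muscle marker score of -0.89, against 0.51 to 0.61. Mut-101 male replicate 2 had a muscle marker score of 0.28, against -0.37 to -0.28. WT-6 female replicate 1 had a trachea and ring gland score of 0.27, against -0.18 to -0.12. It was also the only WT-6 array with a high level of the ring gland gene spok.

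Arrangements of the arrays were counted for the other comparisons too. For C96Y against wild-type proinsulin only the real split gave as many calls (1 of 100 splits, 1943 calls in a fit of split and sex, highest other 2). The same held for C96Y against non-transgenic discs (1 of 100, 581 calls, highest other 20) and for males against females (1 of 100, 920 calls, highest other 290). It also held for C96Y in males (1 of 35, 180 calls, highest other 6) and in females (1 of 35, 244 calls, highest other 7). For WT-24 against WT-6 the real split was again the only one (1 of 34, 96 calls, highest other 2). These counts argue against chance among arrays, but 34 or 35 splits allow no smaller share, and shares were not adjusted over the comparisons. Chance cannot be excluded for wild-type proinsulin against non-transgenic discs. There 7 of 100 splits gave as many as the 1 call of this fit, and the highest other gave 64, the source of which was not tested. For the interaction the count says nothing about chance, since with 0 calls every permutation of sex gives as many (100 of 100, with 6 the highest). These splits exchange single arrays, and arrays of a line are not independent. For C96Y against wild-type proinsulin or non-transgenic discs, in both sexes or 1, they argue against chance among arrays and not against a difference between the lines. With lines as the units of C96Y against wild-type proinsulin, only 3 ways part the 4 lines into 2 and 2, too few for a share under 0.05. The real one gave 2058 calls, the only arrangement of that size (1 of 3), and the highest other 229.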

How the results depend on the processing

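The alternative that leaves out the 2 arrays with fat body transcripts, and the list tests without Mut-101 male replicate 2, were chosen only after the result was seen. For the counts that moved the cause was not tested, except where fewer probe sets or arrays entered.

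Counts are given in the order C96Y against wild-type proinsulin, its line-consistent calls, wild-type proinsulin against non-transgenic, C96Y against non-transgenic, C96Y in males, C96Y in females, Mut-101 against Mut-1, WT-24 against WT-6, males against females. With arrays centred on their medians the counts were 604, 571, 6, 330, 197, 126, 180, 43 and 715. With the number of the description label as a block they were 643, 613, 2, 271, 267, 53, 5, 2 and 366, and 3 for the interaction. With only the arrays of the groups compared, counts fell to 2 for wild-type proinsulin against non-transgenic, 395 in males, 373 in females and 225 between the mutant lines. Without Mut-1, C96Y gave 724 calls against wild-type proinsulin and 338 against non-transgenic, without WT-24 1049 against wild-type proinsulin, and without WT-6 wild-type proinsulin gave 28 against non-transgenic. Line as a random block gave 4 for wild-type proinsulin and 734 for C96Y against non-transgenic, and line means 0 for C96Y against wild-type proinsulin (limma). Without the 2 arrays with fat body transcripts C96Y gave 515 against non-transgenic. The floor gave 1 call for the interaction, and males against females gave 830 with quantile normalization and 576 with the upper 40% of probe sets. Other settings stayed within 1.5 times of each count.

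With each of the 20 arrays left out in turn, counts ranged from 1491 to 2160, 1398 to 2015, 3 to 27, 572 to 1207, 359 to 855, 245 to 725, 167 to 489, 59 to 103 and 710 to 1516 in the same order, and from 0 to 3 for the interaction. Where this left 1 array in a group, that array was taken to vary as the other groups did. Arrays that moved a count beyond 1.5 times are named with each comparison.

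Of 13143 values of 388 named calls 11014 kept direction and threshold, 2120 kept direction and lost the threshold and 9 changed sign. In C96Y against wild-type proinsulin pros changed to 0.0165 without Mut-1, and in wild-type proinsulin against non-transgenic pins to 0.00385 without WT-6. In males against females, where median centring moved all probe sets by -0.10, it turned crc (-0.0517), wgn (-0.0183), GstD1 (-0.0358), RpL34a (-0.0370), RpL17 (-0.0559), ND-B16.6 (-0.00349) and nrv2 (-0.0262). Of 1932 values of 252 list tests 1744 kept their side of the threshold, 127 lost it and 61 gained it. A change of direction was counted only for lists past the threshold in the main test, and 0 were found. Without Mut-101 male replicate 2, 244 of the list tests kept their side, 3 lost the threshold and 5 gained it.

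Replicate numbers in the sample titles did not pair the arrays. Over 45 pairs of groups the correlation of same-numbered deviations had a median of -0.03 and ran from -0.47 to 0.29. With this replicate block the counts were 1846, 1734, 11, 1004, 673, 556, 311, 84 and 1081 in the same order and 0 for the interaction. Numbers of the description label did not pair them either (median r -0.02 for equal and 0.02 for unequal numbers). They were spread unevenly over the lines, so the lower counts with them as a block cannot tell a batch from a loss of precision. The additive model of line and sex could not be fitted to males, females or the interaction.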

Other observations

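The test of the X chromosome count against tissue composition or scaling and that of the lines as the source of high spok levels were chosen only after the result was seen.

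Genes of steroid hormone synthesis, which belong to the ring gland, an endocrine organ near the brain, varied between single arrays of the same line; those named here were picked after their values were seen. The Halloween gene spok ranged from 4.27 to 12.65 on the log2 scale, with 9 arrays at 8.96 or above and 11 at 7.22 or below. High arrays numbered 3 of 4 in non-transgenic, 1 of 4 in WT-6, 3 of 4 in WT-24, 2 of 4 in Mut-101 and 0 of 4 in Mut-1 discs. The related gene sad ranged from 7.43 to 11.87, and Akh, a hormone gene of the same organ, from 7.14 to 11.34. Over the arrays with high and low spok the medians were 9.73 and 7.55 for sad and 8.11 and 7.59 for Akh. Akh did not follow spok in every array. It was highest in non-transgenic male replicate 1 (spok 12.33) and lowest in WT-6 female replicate 1 (spok 11.77). Fat body transcripts stood out in 2 arrays, non-transgenic male replicate 2 (score 2.44) and WT-24 female replicate 1 (1.79).

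The largest unnamed change in C96Y discs was at a probe set that pairs with no single gene and rose by 3.67 ± 0.0644 (SE; limma adjusted p = 3.65e-13). Chromosome 4 genes lay lower in C96Y than in wild-type discs, with a median log2 change of -0.10 over 55 genes, against -0.01 to 0.01 on the other arms, a difference that was not tested.

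Ring gland tissue in some dissections may account for the high spok levels, although Akh was not high in all arrays with high spok. Over the 9 arrays with high spok, spok correlated with the mean of 8 further ring gland genes fixed before they were looked at (Pearson r = 0.91, exact permutation p = 0.00124; Spearman rho = 0.98, exact p = 4.96e-05; 1 relation tested), and r was 0.98 without the 2 arrays farthest from the median. A difference between the lines is argued against as the whole cause, since arrays of the same line and sex stood far apart. On the log2 scale spok was 11.31 and 5.91 in non-transgenic females, 11.77 and 5.07 in WT-6 females, and 4.84 and 12.10 in WT-24 females. In every other group both arrays were high or both low. A further difference between the lines stays open, since the number of high arrays differed between them, and that 4 of 5 lines held both high and low arrays restates the pattern. No biological explanation was tested.

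Genes that differed between WT-24 and WT-6 were absent from the X chromosome. Of 81 calls with a chromosome 0 lay among 1359 X genes, where 13.8 would follow from the genes tested, and 2R had 4 against 16.8. The X held fewer calls than the other chromosomes (one-sided Fisher's exact p = 2.44e-07, a test that treats genes as independent), which restates the pattern. How tissue composition or scaling would spread calls over chromosomes was not measured, so they cannot be told apart from other sources. A larger spread on the X is argued against, since its median SE was 1.05 times that of the autosomes. Sequence variants under single probe sets cannot be told apart from changes in expression, because only 7 other probe sets of the called genes were tested (85.7% with the same sign). A difference in autosomal genetic background between the lines also stays open and was not tested. Between the mutant lines 33 of 311 calls lay on the X (two-sided Fisher's exact p = 0.00155). These were 2.43% of the X genes tested, again a smaller share than the 3.64% to 4.66% on the other arms.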
